A study of Homo sapiens with 6 samples.

How the data were processed

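Total RNA of MCF10Ca1h cells, a human breast cancer cell line of the MCF10A lineage, was measured on 6 Clariom S Human arrays. The cells carried a lentiviral control shRNA (shCON, 3 arrays) or an shRNA against PADI4 (sh80, 3 arrays) and had been selected with puromycin, per the labels' protocols. RNA was extracted with TRIzol and its quality was examined on an Agilent Bioanalyzer, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 3 arrays of a group came from separate transductions or cultures, so p-values measure the spread between these arrays, which may be technical.

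The deposited table holds log2 values, 1 column per array and 1 line per probe set, made by the authors with RMA (robust multi-array average), per the submitters' processing notes. RMA subtracts background, normalizes between arrays and summarizes the probes of a probe set. The software, its version, the genome build and whether other arrays were normalized together with these are not given in the sources used here. The deposited log2 values ran from 2.39 to 18.7 with array medians between 6.08 and 6.23, so the arrays did not share 1 identical distribution. They were used as deposited. RMA signal has no detection call and a background that lies above 0, so differences between dim probe sets are understated, and no probe set's level was set against another's as an amount of RNA.

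Of 21448 probe sets, 17709 had 1 gene symbol in the platform annotation, 0 had several and 3739 had none listed. All 17709 matched the RefSeq gene table of assembly GRCh38.p14 by gene ID and took its current symbol, which gave 17687 distinct symbols. The 17709 were tested. No probe set was left out for low signal in the reported test. No coordinates are given because the build behind the probe sets is not named.

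The single comparison was sh80 minus shCON, with all 6 arrays. Differences were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, not robust), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Adjusted p-values below are limma's unless stated otherwise. The same count was taken with an added minimum difference of 2-fold (1 on the log2 scale). For PADI genes an exact two-sided permutation test of 3 arrays against 3 was added, and the smallest p that design can give is 0.1. Values are given as mean ± SD with n = 3 arrays per group, and intervals are limma's 95% confidence intervals. The number of arrays limits the precision of each value.

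Before the data were examined, 31 gene lists were fixed, together with the test, the rule for naming genes and the alternatives. Each list was tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01, 1 probe set per gene (the brightest on average) and Benjamini-Hochberg adjustment over the 31 lists. Camera asks whether a list moves relative to other genes. Fry was run beside it, which asks whether a list's genes move one way on balance or, in its mixed form, in either direction, with no reference to other genes. For each list the members past 0.05 were counted over all genes tested and adjusted over the list alone. The lists covered breast stem cell markers, pluripotency factors, epithelial junction, mesenchymal and EMT, basal, luminal, estrogen response and epidermal differentiation genes. Others held p53, TGF-beta, BMP and ID, Wnt, Notch, YAP and TAZ, MAPK, interferon, NF-kB and antigen presentation genes. The rest held mitotic, DNA replication, MYC and nucleolar, ribosomal protein, oxidative phosphorylation, glycolysis and hypoxia, cholesterol, stress response, linker histone and peptidylarginine deiminase genes, and markers of haematopoietic, fibroblast and endothelial cells. Listed genes whose symbol has no named probe set here were not analysed. That left 10 of 20 basal genes and 22 of 39 ribosomal protein genes.

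The rule for named genes took the PADI family. It also took up to 12 genes per direction with the largest difference among those past 0.05 whose arrays did not overlap between groups and whose brighter group reached the median of tested probe sets, skipping uncharacterized loci, pseudogenes and small RNAs. From a list past the threshold it took up to 4 members in the list's direction and 2 in the other. From the other lists it took up to 2 past 0.05, and from the breast stem cell and pluripotency lists the member with the largest difference. Because a single gene passed, the first part was applied again at an adjusted p under 0.25, chosen after the values were seen. Members past the threshold over their list alone, and genes named in describing single arrays or the stem cell lists, were also chosen after their values were seen.

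The replicate numbers 1 to 3 occur in both groups. Whether they pair the arrays was checked by correlating, across probe sets, each array's deviations from its group mean. Same-numbered arrays gave 0.35, 0.23 and 0.21, and each array correlated best with its own number in the other group, so the numbers were taken to pair the arrays. This pairing comes from the data and the titles, since no label names a shared day or batch. With so few arrays such a match can also arise by chance, and its chance level was not computed. The reported test has no block, as fixed beforehand, and the blocked result stands beside it where a call differs.

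The procedure was tested on simulated data in which 200 of 17709 probe sets, 50 per size, differed by known amounts at the spread of these arrays. It called 6% of those with a log2 difference of 1, 66% at 2, 80% at 3 and 90% at 4, and 7 of 17509 unchanged probe sets. These rates hold for 200 changed probe sets, and the adjusted threshold is stricter where fewer are called. For the list test the NF-kB list was lowered by 1.3 log2 in simulated data, close to its median difference in the real data (-1.34). It was called, and 0 of 30 other lists were. Genes were simulated independently of each other, so this is no check of lists whose members vary together. In the real data the estimated inter-gene correlation of the NF-kB list was 0.11.

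Alternatives fixed beforehand were the replicate number as a block, a filter on low values, all probe sets in the table, quantile normalization applied again, arrays centred on their medians, cyclic loess, an intensity trend, robust hyperparameters, an equal-variance test per probe set, each array left out in turn, limma's treat at 1.5-fold, an estimated inter-gene correlation, fry, and averaging all probe sets of a gene. Array weights, leaving out the 2 arrays least correlated with the rest, and removal of a per-array trend on gene length and gene density (alone and with the block), and an estimated inter-gene correlation without sh80 replicate 1 or sh80 replicate 3 were added after seeing the data. Gene density is the number of protein-coding genes starting within 500 kb in the same RefSeq table, and the trend was a spline with 4 degrees of freedom per property.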

Results

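Gene expression was profiled in MCF10Ca1h cells carrying a control shRNA (shCON) or a shRNA against PADI4 (sh80), with 3 arrays in each group. PADI4 is a peptidylarginine deiminase, an enzyme that converts arginine in histones and other proteins to citrulline. The series title places the gene in the regulation of breast cancer stem cells, and the comparison asked which transcripts differ when it is targeted. Correlations between arrays over all 21448 probe sets ran from 0.907 to 0.992. The arrays of a group did not lie close together in every case. For shCON replicate 2 the correlations were 0.983 and 0.985 with sh80 replicates 2 and 3. They were 0.980 and 0.950 with shCON replicates 1 and 3, and 0.962 with sh80 replicate 1. The mean correlation with the other 5 arrays was lowest for shCON replicate 3 (0.937) and sh80 replicate 1 (0.948). The first principal component held 51.8% of the variance and set shCON replicate 3 apart (-102 on it), with the sh80 arrays (25.9 to 54.3) above all shCON arrays (-102 to 8.14), and the second held 30.2% and set sh80 replicate 1 apart.

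**Figure D1:**
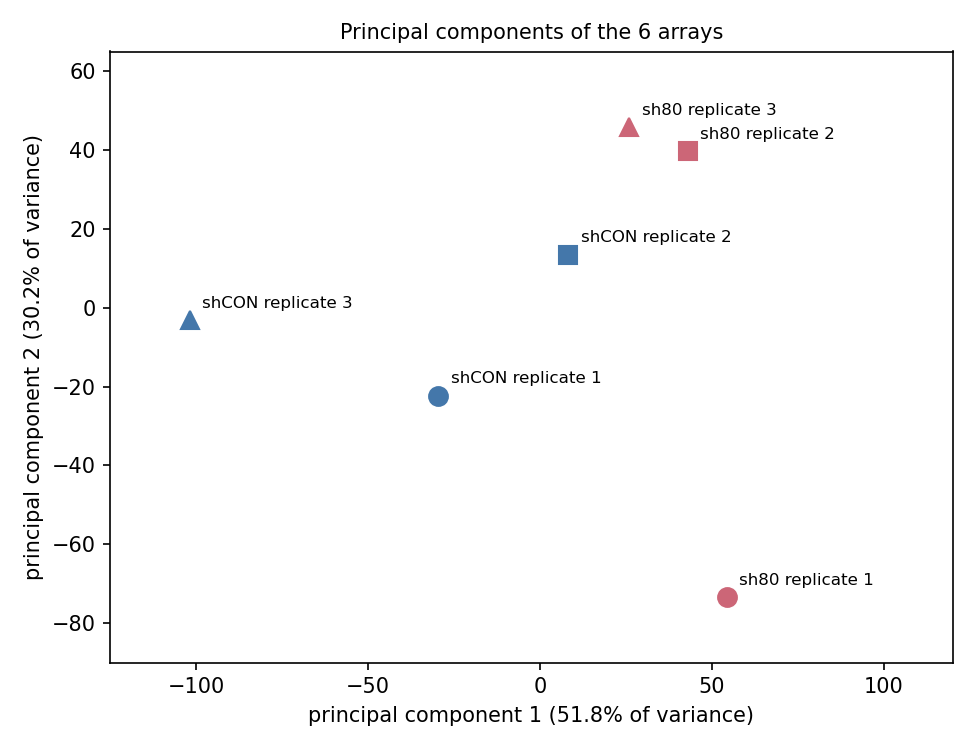
Principal components of the 6 arrays, with component 1 (51.8% of variance) on the horizontal axis and component 2 (30.2%) on the vertical axis. Blue marks shCON and red sh80, the symbol gives the replicate number, and sh80 replicate 1 lies far from the other sh80 arrays on component 2 (-73.5 against 39.7 and 45.8).

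The targeted gene comes first. The PADI4 probe set gave 4.04 ± 0.11 in shCON and 4.004 ± 0.14 in sh80 (log2, SD, n = 3), a difference of -0.04 with a 95% interval from -0.50 to 0.43 and a limma adjusted p of 0.951. The exact two-sided permutation p was 0.6, where 0.1 is the smallest that 3 arrays against 3 can give. Its single array values were 4.08, 3.92 and 4.12 in shCON and 4.06, 3.85 and 4.11 in sh80. The PADI4 probe set was at the 12.9th percentile of all probe sets and the 54.7th percentile of 349 olfactory receptor probe sets (median 3.92), genes of the olfactory epithelium. At that signal the arrays gave no check of the knockdown in either group, and the direction of every difference below rests on the labels. The sign of the PADI4 difference changed when quantile normalization was applied again (0.049) and with cyclic loess (0.051). It also changed without shCON replicate 3 (0.0042) and without sh80 replicate 2 (0.041).

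Other PADI genes did not pass either. PADI3 gave 12.8 ± 0.62 in shCON and 11.9 ± 1.51 in sh80, with sh80 replicate 1 at 13.6 and the others at 11.0 and 11.0. PADI2 gave 10.9 ± 0.65 and 10.9 ± 0.10. PADI1 differed by 0.67, with sh80 replicate 1 at 6.92 and the others at 9.47 and 9.58 (shCON mean 7.98). PADI6 differed by -0.59. None of the 5 genes passed (limma adjusted p from 0.568 to 0.997), and their list had a median of -0.04 and a camera adjusted p of 0.802.

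PTGS2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, rose in sh80 by 2.71 on the log2 scale, a 6.56-fold difference (95% interval of the log2 difference 2.27 to 3.16). Its signal was 6.27 ± 0.10 in shCON and 8.98 ± 0.08 in sh80 (SD, n = 3), higher in 3 of 3 arrays, with a limma adjusted p of 0.0431. It was the only probe set of 17709 past 0.05, so 1 rose, 0 fell, and 1 passed with the 2-fold minimum. At an unadjusted p under 0.05 there were 2192 probe sets, 1299 higher and 893 lower, where 885 are expected by chance. With an intensity trend PTGS2 lost its call (adjusted p 0.0538, in a range of 0.00132 with array weights to 0.549 without shCON replicate 1) and C3 was the 1 probe set called, and the equal-variance test called 2, PTGS2 and ZNF680. In 3175 probe sets (17.9%) the groups did not overlap, where chance gives 10% on average for 3 against 3. Probe sets vary together, so a single split can exceed 10% without a group effect, and this share was not taken for other splits. With the replicate number as a block limma called 0 probe sets, with 2883 at an unadjusted p under 0.05. The count depended on single arrays, with 219 past the threshold without shCON replicate 2, 30 without sh80 replicate 1 and 0 without any of the other 4. Leaving out shCON replicate 3 and sh80 replicate 1 together, chosen after seeing the data, gave 129.

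At an adjusted p under 0.25, chosen after the values were seen, 17 probe sets were higher and 31 lower in sh80. The 24 genes named from them kept the sign of their difference in all alternatives in which they were tested. That was largely set in advance, because the rule took only genes whose arrays did not overlap between groups. In the reported test none of the 24 except PTGS2 passed 0.05. Some other settings called more of them. The filter on low values called C3, ICAM1, ITGB3 and ADARB1 besides PTGS2, 22 were called without shCON replicate 2, and 7 were called without sh80 replicate 1. Settings chosen after seeing the data called 10 (length and density correction), 19 (without the 2 arrays above) and 24 (array weights). Among those with higher values, VCAN, which encodes the matrix proteoglycan versican, had a difference of 4.14 (7.93 ± 1.11 to 12.1 ± 0.65, adjusted p 0.183). HAS2, a hyaluronan synthase, had a difference of 2.22 (adjusted p 0.19), and SEMA3A, a secreted guidance factor, one of 3.40 (adjusted p 0.216). TCN1, a vitamin B12 carrier, went from 12.6 ± 0.87 to 15.5 ± 0.08. ELL2, a transcription elongation factor, differed by 2.57 (adjusted p 0.0847). The zinc finger genes ZNF91 (2.33), ZNF680 (2.04) and ZNF577 (1.87), the transcription factor KLF12 (2.18), the glutamate receptor gene GRIK2 (2.14) and the kinase STK17B (2.02) made up the rest.

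Among those with lower values, C3, the central complement component, had 15.6 ± 0.21 in shCON and 11.2 ± 0.67 in sh80, a difference of -4.43 (adjusted p 0.0615). CCL20, a chemokine, had the largest difference in that direction, -4.55 (adjusted p 0.216). ITGB3, integrin beta 3, had 11.4 ± 0.26 and 7.36 ± 0.71, a difference of -3.999 (adjusted p 0.0665). ICAM1, a leukocyte adhesion receptor, differed by -3.42 and AXL, a receptor tyrosine kinase, by -2.84 (both adjusted p 0.0765). MMP9, a matrix metalloproteinase, differed by -3.35 and BSG, the surface glycoprotein basigin, by -2.92. ADARB1, an RNA-editing adenosine deaminase, differed by -3.04 (adjusted p 0.0665). The others were HPCAL1 (-2.95), TXNDC5 (-2.78), SLIT3 (-2.64) and SGPP2 (-2.63). TXNDC5 shares sequence with a readthrough transcript, so its probe set may read both.

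**Figure D2:**
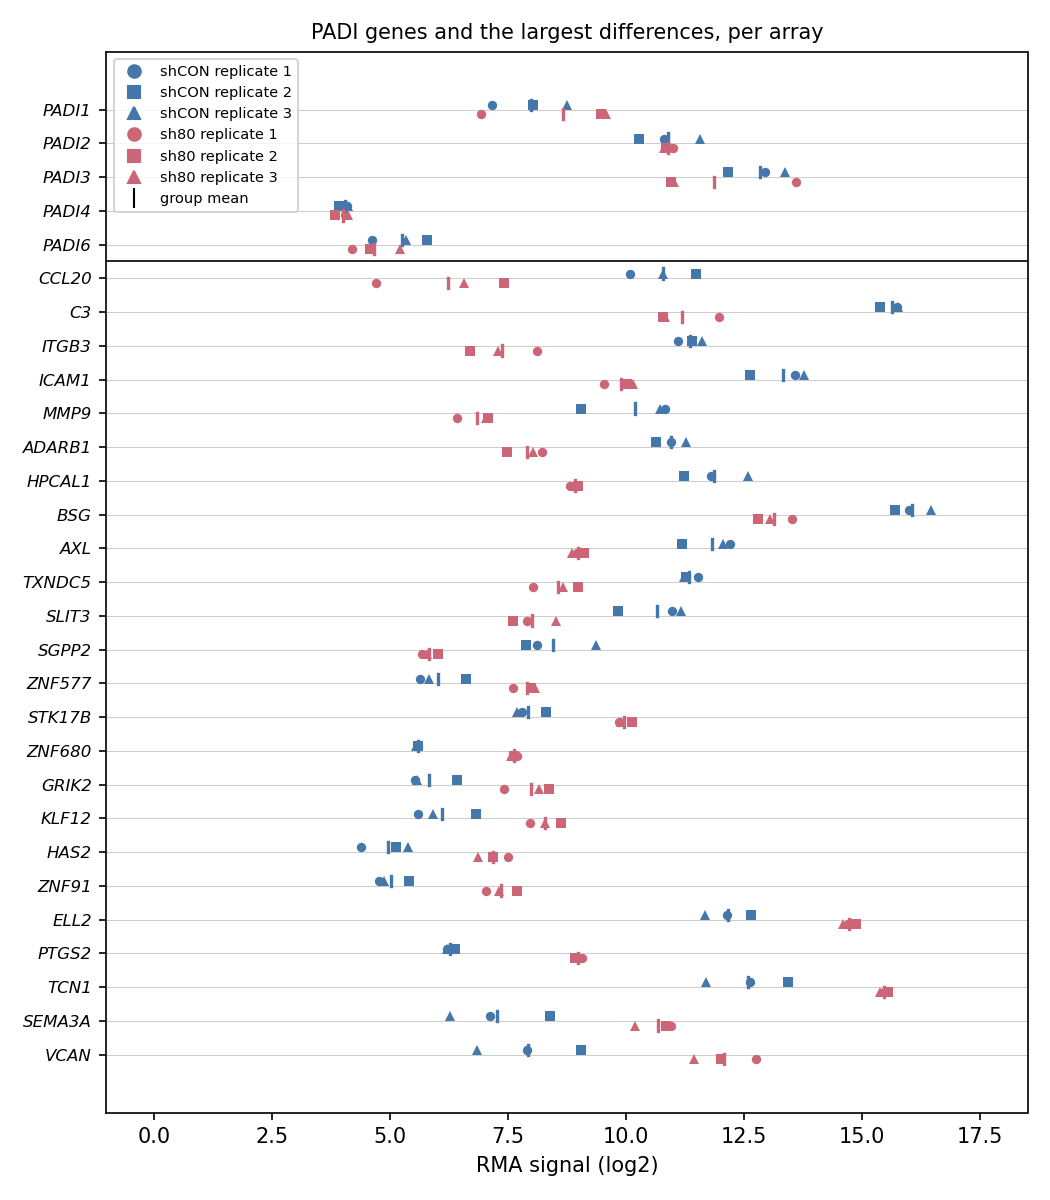
RMA signal (log2, horizontal axis) of the PADI genes, above the line, and of the 24 genes with the largest differences at an adjusted p under 0.25, below it. Each point is an array (blue shCON, red sh80, symbol by replicate number) and each vertical bar a group mean; PADI4 lies near 4.04 in shCON and 4.004 in sh80, and PTGS2 is the gene that passed 0.05.

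Genes of NF-kB and inflammatory signalling were lower in sh80 as a list. Of 33 listed genes 28 were measured, with a median difference of -1.34, and 26 were lower and 2 higher at any size. Adjusted over the list alone 10 fell, 1 rose (PTGS2) and 17 did not pass, and with the replicate block 14 fell and 1 rose. Over all genes tested 0 fell and 1 rose. The 10 were C3 and CCL20 as above, ICAM1, CXCL1 (-2.48, a neutrophil chemokine), TNFAIP2 (-1.62), LCN2 (-1.54, an iron-binding acute-phase protein), IL32 (-2.78), LIF (-2.03), SAA1 (-1.45) and CSF1 (-2.29, a macrophage growth factor). The camera adjusted p was 3.43e-09. That call was lost with an estimated correlation (adjusted p = 0.703 with an estimated correlation, and adjusted p = 0.922 with the replicate block as well). Fry gave an adjusted p of 0.0624 for 1 direction and 0.000474 for either. Among members that did not pass, IL1B had 16.9 ± 0.29 in shCON and 10.3, 15.1 and 14.7 in the sh80 arrays, and the NF-kB inhibitor genes TNFAIP3 and NFKBIA differed by -1.81 and -1.23. The array set apart on the second principal component, sh80 replicate 1, had the lowest list median, and without it the list's difference was -0.74 instead of -1.34. Within same-numbered pairs the median was -1.70, -0.60 and -0.63, with 27, 25 and 23 of 28 members lower.

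**Figure D3:**
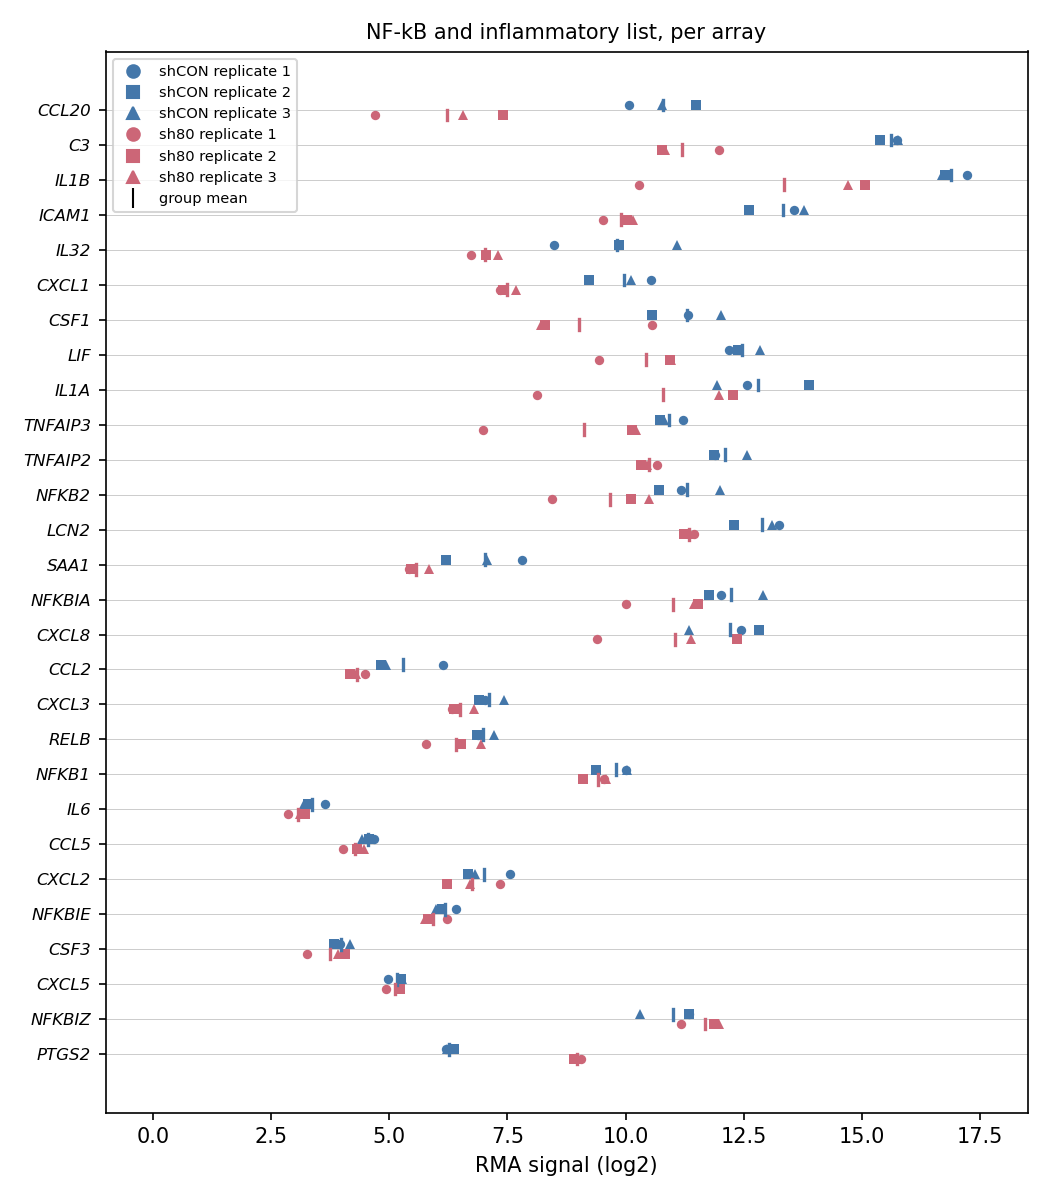
RMA signal (log2, horizontal axis) of the 28 measured members of the NF-kB and inflammatory list, ordered by their difference. Each point is an array (blue shCON, red sh80, symbol by replicate number) and each vertical bar a group mean; PTGS2 and NFKBIZ, at the bottom, are the 2 members with higher means in sh80.

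Stem cell genes, the subject named in the title, did not pass as lists in the reported camera test. The 21 measured breast stem cell markers had a median of -0.21, with 14 lower and 7 higher at any size. That median is the difference of CXCR1, dim at 4.13 ± 0.12 and 3.92 ± 0.20, where background limits what a difference can show. KIT, TSPAN8, PROM1, CXCR4, ALDH1A1, LGR5, LGR6, MSI1 and ABCG2 were also dim (group means of at most 5.38), so the counts by direction include them. Over all genes 0 passed, and adjusted over the list alone 1 fell, ITGB3 (2 with the replicate block). The camera adjusted p was 0.231. The list passed, with lower values, in fry for 1 direction (adjusted p 0.045) and in 3 camera alternatives chosen after seeing the data: the correction for gene length and density (0.0487), that correction with the replicate block (0.0439), and leaving out shCON replicate 3 and sh80 replicate 1 (0.0443). With an estimated correlation and all arrays it did not pass (adjusted p = 0.896 with an estimated correlation). CD44 differed by -0.47, CD24 by 0.71 and ALDH1A3 by 0.02, and none passed. NGFR had 13.7 ± 0.46 in shCON and 13.5, 8.03 and 7.75 in the sh80 arrays. The 19 pluripotency factors had a median of -0.25 (camera adjusted p 0.174), and 0 passed either count. The largest difference among them was that of TFCP2L1 (-1.10). SOX2 (-0.60), MYC (-0.60) and NANOG (-0.25) did not pass. NANOG, whose difference is the median of this list, was dim at 4.41 ± 0.18 and 4.15 ± 0.20.

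In the other 28 lists the camera adjusted p lay between 0.174 and 0.907, and 0 members passed over all genes tested. Adjusted over the list alone, 3 TGF-beta response genes fell, LTBP2 (-1.35), ANGPTL4 (-0.83) and TGFB1 (-2.12), against a list median of -0.18 (0.06 without sh80 replicate 1, the array with the lowest list median, -0.69 against 0.07 and 0.04 in the other sh80 arrays). SERPINA1 (-2.24) fell in the estrogen response list, which had a median of -0.09. AXL fell in the mesenchymal and EMT list (median -0.13) and in the YAP and TAZ list (0.04, where camera's direction was lower). Adjusted over the list alone 0 members passed in the remaining lists. With the replicate block these counts were 2 lower and 3 higher for TGF-beta, 3 lower and 1 higher for estrogen response, 1 lower and 1 higher for YAP and TAZ and for MAPK, 1 higher for p53 targets and 2 higher for basal genes.

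Among cell identity lists the median was -0.002 for epithelial junction genes, -0.39 for basal, -0.05 for luminal and -0.19 for epidermal differentiation genes. Signalling lists gave 0.20 for p53 targets, -0.20 for BMP and ID targets, 0.09 for Wnt targets (camera's direction was lower), -0.12 for Notch targets, -0.27 for MAPK and immediate-early genes and 0.08 for interferon-stimulated genes. Antigen presentation genes had a median of -0.23. Metabolic and growth lists gave -0.18 for MYC and nucleolar genes, 0.04 for ribosomal proteins, -0.19 for oxidative phosphorylation, -0.37 for glycolysis and hypoxia, -0.02 for cholesterol biosynthesis and -0.05 for the unfolded protein and integrated stress response, with camera's direction higher in the last 2 and in the epithelial junction and luminal lists. Markers of other cell types had medians of -0.10 (haematopoietic), -0.19 (fibroblast and stromal) and 0.04 (endothelial). The sign of many list medians rested on single arrays, and turned for 19 of the 31 lists when 1 array was left out. Without sh80 replicate 1 the median was 0.31 for epithelial junction and 0.015 for basal genes, 0.13 for BMP and ID, -0.016 for Wnt, 0.0069 for Notch and -0.011 for YAP and TAZ targets, -0.066 for interferon-stimulated genes, -0.026 for ribosomal proteins and 0.12 for stress response genes (camera adjusted p from 0.185 to 0.987). In basal genes that array had a median of -0.75 relative to the shCON mean, and the other sh80 arrays -0.0039 and 0.11. The p53 median was -0.20 without sh80 replicate 3 and -0.0071 without shCON replicate 2. Luminal, DNA replication, cholesterol, haematopoietic, endothelial and peptidylarginine deiminase lists also had the other sign without another array, and with another scaling the sign turned for epithelial junction, YAP and TAZ, ribosomal protein, endothelial and peptidylarginine deiminase lists.

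Proliferation lists did not separate the groups and were set by sh80 replicate 1. Mitotic genes had a median difference of 0.28 (camera adjusted p 0.674), DNA replication genes -0.07 (0.907) and linker histones 0.10 (0.804, where camera's direction was lower). Relative to the shCON mean, the median of the 32 mitotic genes was 2.39 in sh80 replicate 1 and -0.60 and -1.15 in the other sh80 arrays. It was 0.73, 0.0028 and -0.59 in shCON replicates 1, 2 and 3. Without sh80 replicate 1 the difference was -0.88 for mitotic genes (camera adjusted p 4.0e-08), -0.75 for DNA replication genes (2.76e-06) and -0.95 for linker histones (0.0144). None of these held with an estimated correlation (adjusted p = 0.551 for mitotic genes, 0.596 for DNA replication genes and 0.551 for linker histones with an estimated correlation). MAPK, antigen presentation, oxidative phosphorylation and glycolysis lists also passed without that array at the preset correlation, with adjusted p from 0.551 to 0.583 with an estimated correlation. The mitotic genes passed with the opposite sign, 0.86, without sh80 replicate 3 (camera adjusted p 0.0222, and adjusted p = 0.824 with an estimated correlation).

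**Figure D4:**
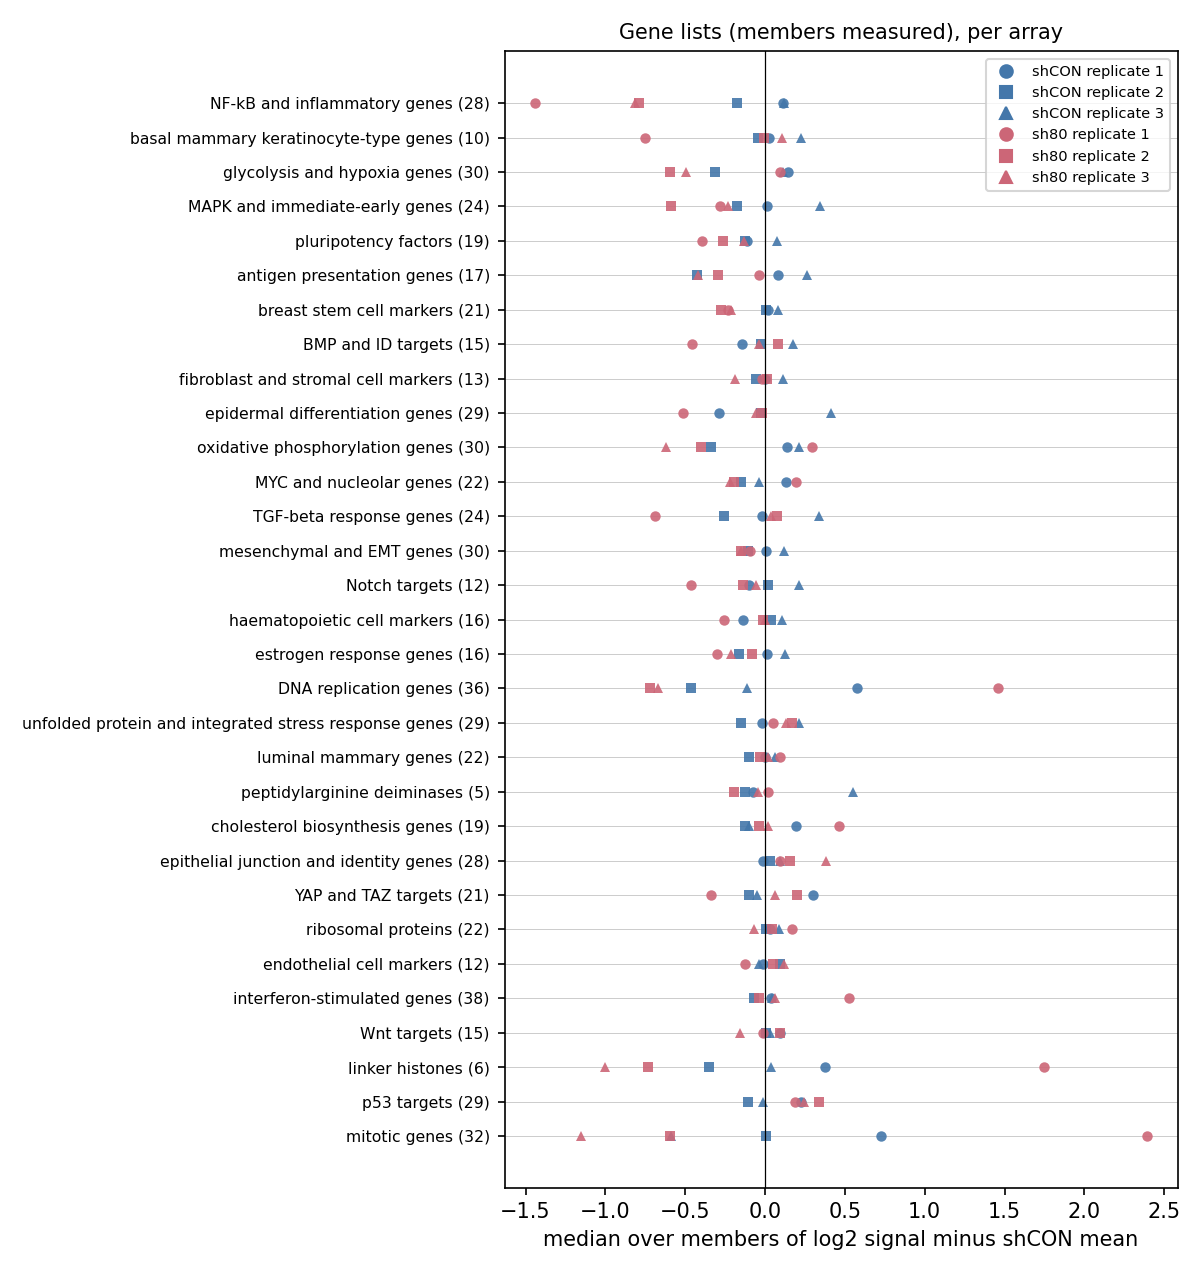
Median over a list's members of the log2 signal minus each gene's shCON mean (horizontal axis), for the 31 lists with the number of members measured in brackets. Each point is an array (blue shCON, red sh80, symbol by replicate number); the mitotic median is 2.39 in sh80 replicate 1, against -0.60 and -1.15 in the other sh80 arrays.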

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

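Array weights, leaving out the 2 arrays least correlated with the rest (shCON replicate 3 and sh80 replicate 1), the correction for gene length and gene density, and an estimated correlation without sh80 replicate 1 or 3 were chosen after seeing the data; the other alternatives were planned. The NF-kB list median stayed below 0 in all alternatives, from -1.62 to -0.74, and its camera call held in the 18 with the preset correlation (largest adjusted p 6.32e-07). These 18 share the preset correlation, with which splits that mix shCON and sh80 arrays also gave a camera p down to 1.02e-04. The call itself depended on that setting. It was lost with an estimated correlation (adjusted p = 0.703 with an estimated correlation) and with fry (0.0624), both at the median of -1.34. The PADI4 difference lay between -0.14 and 0.05, with no adjusted p under 0.609, and was 0.049 after quantile normalization again and 0.051 with cyclic loess. The replicate block gave 0 changed, 0 higher and 0 at least 2-fold, and changed no other call, camera's included, apart from the counts adjusted over a list alone, which are given with their lists.

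The filter on low values gave 5 changed probe sets, 4 lower, 5 of them at least 2-fold, and 2 lists past 0.05 (NF-kB and antigen presentation). Centring arrays gave 2 changed, 1 lower, 2 at least 2-fold, and moved the median of all probe sets from -0.06 to -0.11. The intensity trend gave 0 higher and 1 lower (C3). The equal-variance test gave 2 changed, 2 higher and 2 at least 2-fold. Treat at 1.5-fold gave 0, and the estimated correlation left 0 lists with all arrays, without sh80 replicate 1 and without sh80 replicate 3 (in the last 2 the NF-kB medians were -0.74 and -1.50, with adjusted p = 0.551 and 0.824 with an estimated correlation). Leaving out 1 array gave 0 to 219 changed, 0 to 188 higher, 0 to 31 lower, 0 to 219 at least 2-fold, 1 to 8 lists at the preset correlation and PADI4 differences of -0.099 to 0.041. Array weights gave 2210 changed (1315 higher, 895 lower, 1680 at least 2-fold), 7 lists and 17 NF-kB members lower adjusted over the list alone. Leaving out the 2 arrays gave 129 changed (47 higher, 82 lower, 129 at least 2-fold) and 10 lists, breast stem cell markers among them. The length and density correction gave 10 changed (3 higher, 7 lower, 10 at least 2-fold) and 2 lists (NF-kB and breast stem cell markers), and with the replicate block 0 changed, 0 higher, 0 at least 2-fold and the same 2 lists. Leaving out 1 array moved the mitotic median between -0.88 (without sh80 replicate 1, a reversal) and 0.86, and that of linker histones between -0.95 (the same array) and 0.51. The mitotic median also reversed to -1.04 with array weights and -1.27 without the 2 arrays, and linker histones to -0.75 in the latter. Apart from fewer arrays or probe sets tested, the cause was not tested. Of the other results, 539 list and 989 gene values kept their sign and their side of 0.05, whatever their change in size. With the sign kept, 22 and 115 gained a call and 7 gene values lost theirs. The sign of 94 and 22 turned with no call in either setting. The robust setting and the equal-variance test were not run for the lists, since camera takes neither. At the signal of PADI4, background limits what a difference can show.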

Other observations

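The per-array descriptions, the zinc finger genes, the counts at a 2 log2 gap, the shares under 10%, the shares in the other shCON arrays, the interval for the change made by the correction, the shares over 100%, the test of array-to-array range, the ZNF differences within pairs, and all counts over other splits were chosen after the result was seen. The tests of the length and density trend, of exchanged labels and of mixed material were written down before theirs was seen, but the rule deciding that of NF-kB genes was changed afterwards from the interval of the corrected median, by which it was undecided, to the interval of the change.

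The sh80 array with replicate number 1 had a different expression state from the other sh80 arrays. Its signal was over 2 log2 above their mean in 475 probe sets and over 2 log2 below it in 267, whereas sh80 replicates 2 and 3 differed by over 1 in 218. Genes named for it were taken from its extremes. MKI67, a proliferation marker, was 11.9 against 6.14 and 6.23 in the other sh80 arrays and 6.41 to 8.27 in shCON. RRM2, a subunit of ribonucleotide reductase, was 11.0 against 5.19 and 5.38, with 7.52 to 9.98 in shCON. PI3, which encodes elafin, was 8.17 against 17.4 and 17.6, with 17.9 to 18.3 in shCON. SPRR1A, a cornified envelope precursor, was 6.46 against 14.7 and 15.6, and the collagenase gene MMP1 was 6.24 against 16.4 and 16.3, with 10.5 to 12.8 in shCON. The median of 29 epidermal differentiation genes, relative to shCON, was -0.51 there, -0.02 and -0.06 in the other sh80 arrays and -0.29, -0.03 and 0.41 in shCON replicates 1, 2 and 3. That of 36 DNA replication genes was 1.46 against -0.72 and -0.67, with 0.57, -0.47 and -0.11 in shCON replicates 1, 2 and 3. In sh80 replicates 2 and 3, SPARC was 9.14 and 9.09, against 14.0 in sh80 replicate 1 and 13.1 to 13.7 in shCON. No biological explanation of this array was tested.

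The first pattern weighed is the lower NF-kB and inflammatory list. A gene length and density trend as its whole cause is argued against by the change in the median on its removal. The median went from -1.34 to -1.20, a change of 0.14 with a bootstrap interval over members of -0.12 to 0.32. The share of the median kept had its own interval, 79.3% to 120%. Members share the same 6 arrays, so these intervals do not measure the spread between arrays. The corrected median itself had an interval of -1.76 to -0.44, by which the test decides nothing, and part of it may follow the trend. Of 10 splits of the 6 arrays, 1 gave a camera p as small, the real one (1.11e-10, with 1.02e-04 the smallest other), and 10 splits are too few for a share under 0.05. Further splits mixing shCON and sh80 gave a camera p of 1.54e-04, 1.76e-04 and 1.85e-04, and the rest 0.0193 to 0.882. A small camera p at the preset correlation thus also came from mixed groupings. An effect of the shRNA, on PADI4 or on another transcript, stays open as untested, since the series has 1 knockdown shRNA and no usable PADI4 signal.

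The second pattern is the rise from 1 to 219 called probe sets without shCON replicate 2. In 207 of them that array lay between the other shCON mean and the sh80 mean. The same count was 144 and 45 for shCON replicates 1 and 3, over the 219 probe sets with the smallest p without each. Over all probe sets, shCON replicate 2 correlated more with sh80 replicates 3 (0.985) and 2 (0.983) than with shCON replicate 1 (0.980). A gene length and density trend was not tested as a cause of the rise. For shCON replicate 2, signal relative to the other arrays had rank correlations (Spearman) of 0.10 with gene length and -0.11 with gene density. In the sh80 arrays these were 0.12 to 0.17 and -0.22 to -0.08. They were -0.08 and 0.15 in shCON replicate 1, and -0.25 and 0.32 in shCON replicate 3. By the test written beforehand, exchanged labels of shCON replicate 2 and sh80 replicate 1 remain possible. The exchanged split separated 86 probe sets by at least 1 log2 and the labelled split 77. The exchanged split parts 1 same-numbered pair and the labelled split 3, so variation shared within pairs may widen the gaps of the first. At a gap of at least 2 the counts were 3 and 12, the other way round, and an exchange leaves those 12 unexplained. Mixed sh80 material in shCON replicate 2 also remains possible, since 89.4% of the 188 higher probe sets implied a share within 0.5 to 2 times the median of 63.5%, a wide window (31.7% to 127%). The same test gave 22.9% for shCON replicate 1 (median share 12.1%) and 60.1% for shCON replicate 3 (-29.8%), and 6 of the 219, among them PTGS2 at 2.16% and ITGB3 at -2.36%, implied under 10% for shCON replicate 2 and 10 of the 188 over 100% (up to 136%, and 9 of them inside that window), which a single share leaves unexplained; culture differences were not tested.

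The third pattern is a tilt towards higher values of zinc finger genes with ZNF symbols in sh80. Of 448 probe sets 276 were higher, with a median of 0.15 (0.29 for the 225 on chromosome 19, where the 1031 other genes had -0.19, and 0.088 for the 223 elsewhere), and at an unadjusted p under 0.05 there were 104 higher and 5 lower. The camera p was 3.2e-07 and, as a p with an estimated correlation, 0.0505. Over 17709 probe sets the sh80 minus shCON difference had rank correlations (Spearman) of 0.21 with gene length and -0.29 with gene density. For the ZNF genes such a trend as the cause is argued against, since their median relative to all genes was 0.27 after its removal and 0.20 before. Array-to-array variation unrelated to the groups cannot be told apart from a group effect, because the ZNF median ranged by 0.17 within a group against 0.31 between groups, where the exact permutation p of 0.1 is the smallest possible; within same-numbered pairs the differences were 0.29, 0.29 and 0.35 (exact sign-flip permutation p 0.25, the smallest that 3 pairs can give).

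The other 9 splits of the arrays bear on the counts as follows, and 10 splits are too few for a share under 0.05 in any of them. The real split gave 1 changed, 1 higher, 0 lower and 1 at least 2-fold, and the highest other gave 0 of each, so 1, 1, 10 and 1 splits gave as many. At an unadjusted p under 0.05 the real split gave 2192 probe sets and 2 splits gave as many. The highest other, 2361, set shCON replicates 1 and 3 and sh80 replicate 1 against the rest, which points to a structure of the samples; it keeps pairs 1 and 2 together, and with the replicate block the real split gave 2883. The other 3 splits that part all 3 same-numbered pairs gave 198, 214 and 366. For gene lists past 0.05 all 10 splits gave at least the 1 of the real split, up to 11. Of the 3739 probe sets with no gene listed, limma called 0 past 0.05, with 330 at an unadjusted p under 0.05.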
